A study of Mus musculus with 4 samples.

How the data were processed

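Intestinal mucosa was taken from male A/J and C57BL/6J mice fed a low-fat or a high-fat diet for 2 weeks, with 6 mice in each of the 4 groups, as the study's description gives it. RNA of 2 mice of average body weight was pooled per group, and each pool was hybridised to 1 Affymetrix Mouse Expression Array 430A. Per the labels' protocols, total RNA was made into biotinylated cRNA, the arrays were scanned, and a hybridisation intensity was computed for each transcript from perfect match and mismatch probes with Microarray Suite 5.0 at the manufacturer's default parameters. The deposited values are this intensity, a linear signal per probe set. A common scaling target is not given in the sources used here, and the trimmed means of the arrays differed, at 184, 178, 163 and 147 for A/J low-fat, A/J high-fat, C57BL/6J low-fat and C57BL/6J high-fat.

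Of 22690 probe sets, 64 control probe sets were left out of the gene analysis, and their signals were used only to describe the arrays. Of the other 22626, the platform annotation lists 20380 with 1 gene, 691 with several genes and 1555 with none, and only those with 1 gene were used for genes. Gene numbers of 20351 probe sets were matched to the RefSeq table, which changed 0 symbols. Each array was multiplied by a factor (2.72, 2.80, 3.08 and 3.41, in the order above) that brought the mean of its probe sets, trimmed by 2% at each end, to 500. Scaled signals under a floor of 100 were set to 100, and log2 was taken. Each of 12393 genes was represented by the probe set with the highest mean signal over the 4 arrays, and 8036 genes with a mean scaled signal of at least 100 are called measured. A ratio with a side at the floor is a lower bound and is written as at least that many fold.

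Between 2 arrays, a gene was counted when its ratio was at least 2-fold, with no test, since each group had 1 array. The overlap of lists was set beside the number that independent lists would share among the 6784 genes with any scaled signal of at least 200. The strain and diet effects were tested with limma 3.58.1 in R 4.3.3, as additive terms with 1 residual degree of freedom, moderated variances and Benjamini-Hochberg adjustment. The error term of that fit is the strain-by-diet difference, so it holds array noise and any true difference of response together. A limma value that averages a ratio with a side at the floor is also a bound, and its p rests on signals set to the floor, which cannot vary below it. For each of 42 gene lists (24 of gene function and 18 of cell or tissue markers, 573 of whose 655 genes were found), the median log2 ratio of the measured members was ranked among 10000 random lists of the same size drawn from 20 expression bins with a seed of 1. This rank describes the arrays and is not a test across mice. The lists were written from general knowledge, 41 had measured members, and list members were also adjusted over their list alone. Some genes are on several lists, such as Aldh1a1 on the xenobiotic and retinoid lists, so results of lists that share members are not separate evidence. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.

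The comparisons, tests, lists, main settings, alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. Genes were named by this rule. For each comparison of 2 arrays and for the difference of the diet ratios, the 10 highest and 10 lowest ratios with all signals above the floor were eligible, with the 5 brightest genes each way that had a side at the floor. Also eligible were the 10 genes each way with the largest smaller ratio among those at least 2-fold the same way in both strains or on both diets. So were up to 4 members of each list with the largest ratios, all members at least 2-fold, and any gene at least 2-fold in opposite directions with diet in the strains. Names without a known function were left out.

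The alternatives were quantile normalization, no scaling between arrays, floors of 50 and 200, a pseudocount of 50 in place of the floor, the mean of all probe sets of a gene, leaving out probe sets marked as shared between transcripts, no filter on mean signal, an intensity trend in the moderated variances, 1 factor only, random lists not matched on expression, and leaving out each array in turn, in a fit with 1 factor because 3 arrays leave no residual degree of freedom for 2 factors. The limma fit was tested on simulated data: of 100 genes given a 2-fold change it recovered 69 for strain and 31 for diet, and of 100 given a 4-fold change all 100 for each, with 9 and 0 false calls. Both terms had the same design, noise model and effect sizes, with 1 draw each, so 69 against 31 does not show lower power for diet. The noise was drawn as the fit models it, with no floor and no strain-by-diet effect. The false calls therefore do not check the fit on the real data. In a test on simulated lists of 20 genes in the A/J diet comparison, 9 of 200 lay outside the central 95% with no added shift and 200 of 200 with 0.5 added on the log2 scale. These lists were random genes, like the lists they were ranked among, so the result with no shift was set by the construction. It does not show how lists of genes that vary together would rank.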

Results

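Gene expression was measured in the intestinal mucosa of male mice of 2 inbred strains, A/J and C57BL/6J, at 10 weeks of age and after 2 weeks on a low-fat or a high-fat diet. A/J mice are known to resist obesity on a high-fat diet, and C57BL/6J mice are known to be prone to it. Each of the 4 groups held 6 mice, and the RNA of 2 of these, with an average body weight, was pooled and hybridised to 1 Affymetrix array. There were no replicate arrays, and the number of arrays limits the precision of every value. The p-values rest on the strain-by-diet difference among these 4 pools and on variance moderated over all genes. They do not measure a spread between pools of the same group. The median deposited signal was 57.1 on the A/J low-fat array, 53.8 on A/J high-fat, 48.6 on C57BL/6J low-fat and 43.9 on C57BL/6J high-fat. After scaling, between 58.6% and 60.3% of the probe sets on an array had a signal of at least 100, the floor used for every ratio. The ratio of 3' to 5' signal lay between 0.942 and 1.01 for beta-actin and between 0.783 and 0.825 for Gapdh. Scaled signals of the CreX 3' control probe set were 12094 and 11988 on A/J low-fat and high-fat, and 19458 and 21250 on C57BL/6J low-fat and high-fat. Those of BioC 5' were 821, 608, 1201 and 1614 in that order. A difference between arrays that follows strain cannot be told apart from strain in this design. Across probe sets, which are not independent replicates, Pearson's r was 0.962 between the A/J arrays, 0.976 between the C57BL/6J arrays and 0.928 to 0.951 between strains. The scaled signal of the 5' probe set for 18S ribosomal RNA was 11010 on the C57BL/6J low-fat array, 1675 on C57BL/6J high-fat, 218 on A/J low-fat and 84.4 on A/J high-fat. Its 3' probe set gave 5012, 398, 214 and 182 in the same order. Genes of the exocrine pancreas list other than Zg16, left out after its values were seen because goblet cells also make it, were 0.0196% of the total signal on the A/J high-fat array. Their share was 0.670% on A/J low-fat, 0.665% on C57BL/6J low-fat and 1.06% on C57BL/6J high-fat.

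The comparison of high-fat with low-fat A/J mice asked how the mucosa of the obesity-resistant strain responded to dietary fat. Genes of fatty acid oxidation were higher on the high-fat array, and genes of sugar handling and the interferon response were lower. Me1, the cytosolic malic enzyme that supplies NADPH, was 7.12-fold higher, from a scaled signal of 381 to 2712. Pdk4, the kinase that restrains pyruvate dehydrogenase, was 3.25-fold higher, the fatty acid transporter Cd36 was 2.42-fold higher and the glycerol channel Aqp3 was 2.52-fold higher. Bco1, which cleaves beta-carotene to retinal, was 4.64-fold lower, and Scarb1, a receptor for lipoproteins and an uptake protein for lipids and carotenoids, was 2.54-fold lower. The glucose-6-phosphatase subunit G6pc was 2.49-fold lower.

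By list, the A/J high-fat array was higher in 14 of the 21 measured PPAR-alpha target genes by at least 1.5-fold and lower in 0, with a median log2 ratio of 0.81. Mitochondrial beta-oxidation genes had a median of 0.41, with 7 of 19 at least 1.5-fold higher and 0 lower, among them the carnitine carrier Slc25a20 at 2.15-fold and the enoyl-CoA isomerase Eci1 at 2.08-fold. Peroxisomal beta-oxidation genes had a median of 0.27 over 17 genes, led by the thiolase Acaa1b at 2.14-fold. The cholesterol synthesis list had a median of 0.29 over 19 genes, with Msmo1 at 2.20-fold and Sqle at 1.81-fold. Carbohydrate digestion and sugar metabolism had a median of -0.30 over 15 genes, with 4 at least 1.5-fold lower and 0 higher, among them the triokinase gene Tkfc of fructose breakdown at 1.55-fold and Fbp1 at 1.56-fold lower. Of 19 interferon-induced genes, 5 were at least 1.5-fold lower and 0 higher, with a median of -0.32; Ifit2 was at least 2.73-fold lower and Usp18 1.69-fold lower. Proliferation genes had a median of 0.41 over 24 genes, with 6 at least 1.5-fold higher and 0 lower, and the replication helicase subunit Mcm2 at 2.12-fold. Each of these 7 medians lay outside the central 95% of 10000 random lists matched on expression, and over the 41 lists with measured members 8 lay above it and 6 below. Among the others outside it were T cell markers at 0.36 over 11 genes, macrophage and dendritic cell markers at 0.22 over 12, smooth muscle markers at -0.47 over 9 and the clock list at -0.34 over 14.

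The largest shift on the A/J high-fat array was in digestive enzymes of the exocrine pancreas. Of the 14 measured genes on that list, 13 were at least 2-fold lower than on A/J low-fat, with a median log2 ratio of -5.40 when members at the floor are taken at their bound. The trypsin gene Prss2 had a scaled signal of 12521 on low-fat and 309 on high-fat, chymotrypsinogen Ctrb1 14074 and 235, and colipase (Clps) 7115 and 764. Carboxypeptidase Cpa1 was at least 99.5-fold lower. The exception was Zg16, chosen here after its values were seen, which is also on the goblet cell list and was 1.04-fold higher.

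In all, 64 genes were at least 2-fold higher in A/J on high-fat and 84 lower, of which 12 and 33 are bounds because a side was at the floor. Without the exocrine pancreas list the number lower was 71. A difference between 1 array and 1 array has no replicate check and no test. Of the genes with another measured probe set, it differed by at least 1.5-fold in the same direction for 9 of 15 higher and 14 of 24 lower genes. With a floor of 50 the counts were 143 and 204, and with a floor of 200 they were 40 and 47.

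**Figure D1:**
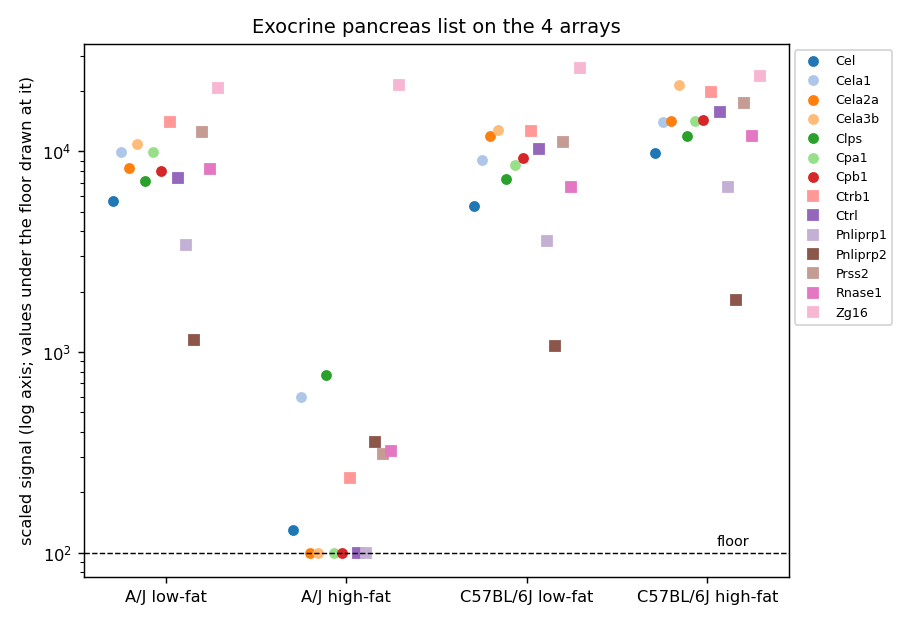
Scaled signal (log axis, values under the floor drawn at the floor of 100) of the 14 measured genes of the exocrine pancreas list on each of the 4 arrays; each marker is 1 gene, offset sideways in the order of the legend, and n = 1 array per group. On A/J high-fat, 13 genes lie below their A/J low-fat signal (Prss2 at 309 against 12521), and Zg16 is at 21447 there.

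In C57BL/6J, the same comparison asked how the obesity-prone strain responded. The fatty acid oxidation genes were higher on high-fat here too, together with genes of xenobiotic and retinoid metabolism, while interferon-induced genes and T cell markers were lower. Me1 was 6.04-fold higher, Pdk4 at least 4.83-fold, Cd36 2.77-fold and Aqp3 at least 2.80-fold. The carboxylesterase Ces1f was 6.30-fold higher, the retinaldehyde dehydrogenase Aldh1a1 3.35-fold and the acyl-CoA synthetase Slc27a2 2.59-fold. Ifit2 was 5.05-fold lower, and the T cell chemokine Ccl5 was 2.29-fold lower. Bco1 was 3.03-fold lower, and the cholesterol efflux pump Abca1 was 3.01-fold lower, with a log2 ratio of -0.82 in another probe set.

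The PPAR-alpha target list had a median log2 ratio of 0.64, with 11 of 21 genes at least 1.5-fold higher and 0 lower. Mitochondrial beta-oxidation had a median of 0.41 over 19 genes, with Acadl at 2.39-fold and Acaa2 at 2.05-fold, and peroxisomal beta-oxidation 0.33 over 17 genes, with Acox2 at 2.25-fold and Hsd17b4 at 2.03-fold. Xenobiotic metabolism had a median of 0.42, with 10 of 27 genes at least 1.5-fold higher and 1 lower: Cyp2j6 was 2.36-fold higher, Ces2a was 2.16-fold higher and Cyp1a1 was 2.85-fold lower. Retinoid handling had a median of 0.61 over 8 genes, with 5 at least 1.5-fold higher and only Bco1 lower by as much. Of 19 interferon-induced genes, 13 were at least 1.5-fold lower and 0 higher, with a median of -0.69. Of 11 T cell and intraepithelial lymphocyte markers, 8 were at least 1.5-fold lower and 0 higher, with a median of -0.66, Cd3d at 2.06-fold and Nkg7 at 2.32-fold lower. Antigen presentation genes had a median of -0.32 over 16 genes, immediate early genes -0.27 over 15 and enteroendocrine markers -0.33 over 14. These immune and immediate early lists were higher on the C57BL/6J low-fat array, the array with the 18S signal of 11010. The xenobiotic and retinoid lists were lower on the same array. The exocrine pancreas list was higher on high-fat, with a median of 0.68 and 12 of 14 genes at least 1.5-fold higher. Each of these 11 medians lay outside the central 95% of random lists, and over the 41 lists 12 lay above it and 5 below. Fibroblast markers lay above it too, at 0.29 over 9 genes, as did adipocyte markers at 0.31 over 6. The adipocyte median changed sign when shared probe sets were left out.

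The gastrokines Gkn1 and Gkn2, normally made by the stomach surface epithelium, were at least 12.2-fold and at least 30-fold higher than on low-fat, with scaled signals of 1220 and 3001. The same array had an exocrine pancreas share without Zg16 of 1.06% of the total signal, against 0.665% on low-fat. Whether these signals came from the mucosa or from other tissue in the pool was not tested. In all, 84 genes were at least 2-fold higher and 54 lower, with 13 and 9 of these as bounds, and no test was possible between 1 array and 1 array. In another measured probe set the difference was at least 1.5-fold the same way for 14 of 32 higher and 3 of 8 lower genes. With the signals left unscaled, the counts were 60 higher and 100 lower.

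The mean effect of diet over the 2 strains was tested with limma over all 4 arrays, as a diet term beside a strain term, which does not require a gene to change in each strain. By that test 34 genes rose and 15 fell on the high-fat diet at a Benjamini-Hochberg adjusted p under 0.05, out of 8036 tested. Me1 rose by 2.71 on the log2 scale (SE 0.197, limma adjusted p = 7.82e-05), and was higher on both high-fat arrays. Also rising were Pdk4 by at least 1.99 (limma adjusted p = 0.000652), Aqp3 by at least 1.41 (limma adjusted p = 0.00485), Cd36 by 1.37 (limma adjusted p = 0.00624) and Acaa1b by 1.17 (limma adjusted p = 0.0197). Tubb2a, a tubulin, rose by 2.49, the class Ib histocompatibility gene H2-Q10 by 2.15, the membrane protein gene Tm4sf4 by 2.07 and the laminin subunit Lamb3 by 2.01, all at a limma adjusted p of 0.000566. The leukotriene C4 synthase Ltc4s rose by 1.93, and Msmo1, an enzyme of cholesterol synthesis, rose by 1.20. Nr0b2, a corepressor induced by bile acids, rose by at least 1.25. Bco1 fell by 1.91 (limma adjusted p = 0.00101), the mannose-binding lectin Mbl2 changed by -1.70 or lower (limma adjusted p = 0.00147) and Ifit2 by -1.89 or lower (limma adjusted p = 0.0022). G6pc fell by 1.07 and Abca1 fell by 1.18, both at a limma adjusted p of 0.0419. Another Abca1 probe set gave log2 diet ratios of only -0.15 in A/J and -0.82 in C57BL/6J. The immunoglobulin light chain segment Igkv14-111 fell by 2.11, and Igkv6-20 changed by -1.53 or lower.

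By list, 3 of the 21 PPAR-alpha target genes rose over all genes tested and 15 when adjusted over the list alone, with 0 falling in either. Mitochondrial beta-oxidation had 0 of 19 over all genes and 8 rising when adjusted over the list alone, and peroxisomal beta-oxidation had 1 of 17 and 5. Of those 8, Slc25a20, Acadl, Cpt1a, Acot2 and Hadha are also among the 15 PPAR-alpha targets, so these counts overlap. Of the fatty acid uptake list's 11 genes, 1 rose over all genes and 2 when adjusted over the list alone. For interferon-induced genes, 1 of 19 fell over all genes and 7 when adjusted over the list alone. Their median was -0.32 in A/J and -0.69 in C57BL/6J. In C57BL/6J the 18S signal was also lower on high-fat, from 11010 to 1675 in the 5' probe set and from 5012 to 398 in the 3' one. In A/J the 5' probe set went from 218 to 84.4, which is under the floor, and the 3' one only from 214 to 182. In the exocrine pancreas list 0 of 14 fell over all genes and 11 when adjusted over the list alone. Those calls come from the A/J high-fat array, since in C57BL/6J the list's median was 0.68, with 12 of 14 at least 1.5-fold higher on high-fat and 0 lower. Xenobiotic metabolism had 3 of 27 rising over all genes, and 3 rising and 1 falling when adjusted over the list alone. The triglyceride synthesis list had 0 of 23 over all genes and 1, the lipid droplet protein gene Plin2, when adjusted over the list alone. Oxidative phosphorylation with 39 genes and the tricarboxylic acid cycle with 17 had 0 in either.

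Counted by size, 19 genes were at least 2-fold higher on high-fat in both strains and 8 lower, where lists of these lengths drawn independently from 6784 genes would share 0.793 and 0.669. Diet ratios of the strains shared no array and correlated weakly across genes, which are not independent replicates (Pearson's r = 0.118 over 8036 genes, and 0.175 without the exocrine pancreas list). With an unadjusted p under 0.05, 751 genes changed by limma. With diet as the only factor, all 4 arrays gave 0 genes by limma and 213 at the unadjusted threshold. The strain difference enters the error of that fit, which makes calls harder. Leaving out an array from it leaves 1 array in a diet group, so this cannot check the diet genes. Without C57BL/6J high-fat, for example, the diet term rests on A/J high-fat alone against the 2 low-fat arrays.

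**Figure D2:**
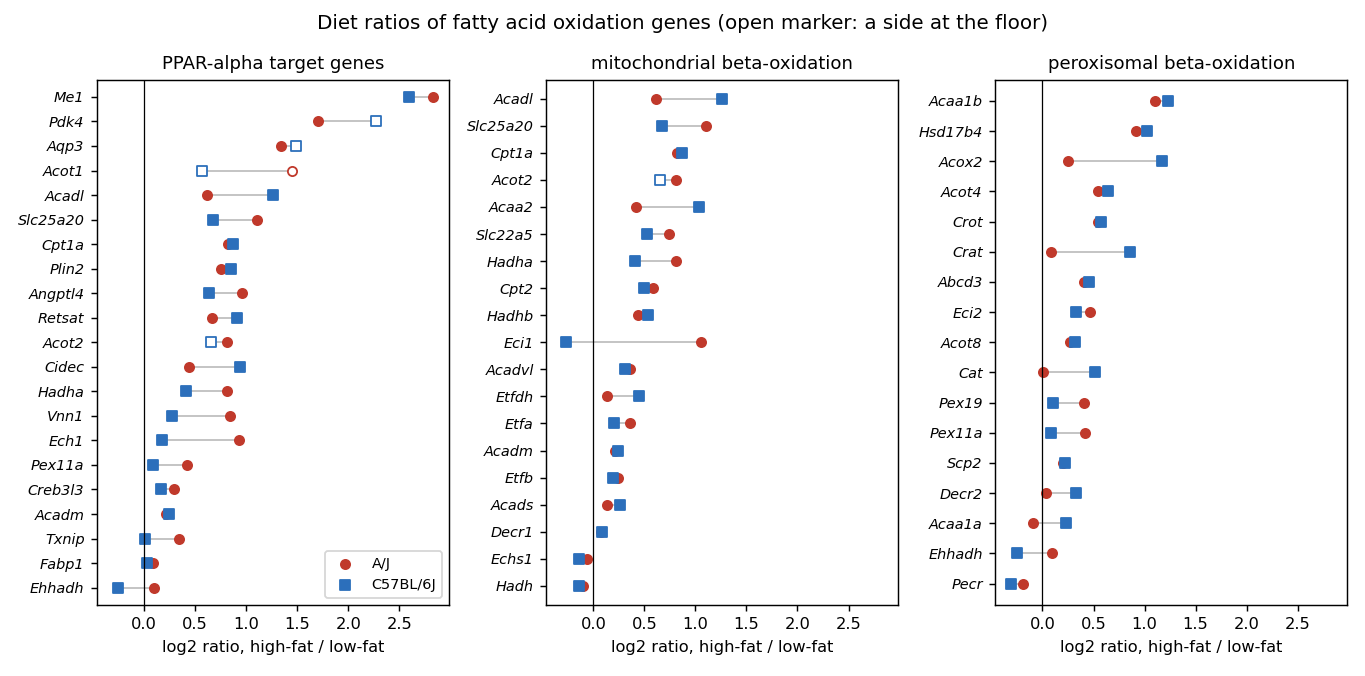
Log2 ratio of high-fat to low-fat signal for each measured gene of the PPAR-alpha target, mitochondrial and peroxisomal beta-oxidation lists, in A/J (circles) and C57BL/6J (squares), with 1 array per group, a grey line joining the strains and open markers where a side was at the floor. The list medians were 0.81, 0.41 and 0.27 in A/J and 0.64, 0.41 and 0.33 in C57BL/6J.

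The low-fat arrays of the 2 strains were compared to ask how the mucosa of A/J and C57BL/6J differed after 2 weeks on the low-fat diet. A/J was higher in genes of fatty acid oxidation, retinoid handling and sugar handling, and lower in antimicrobial, interferon-induced, T cell and cholesterol synthesis genes. Scarb1 was 16.3-fold higher in A/J, from 554 in C57BL/6J to 9018, Bco1 was 14.0-fold higher and Cd36 9.08-fold higher. Pck1, the gluconeogenic enzyme PEPCK, had a scaled signal of 1545 in A/J and was under the floor in C57BL/6J, at least 15.4-fold higher. The sialyltransferase St3gal4 was 118-fold lower in A/J, and the regenerating protein Reg2 was 12.0-fold lower. Inducible nitric oxide synthase Nos2 was at least 5.40-fold lower in A/J, granzyme A (Gzma) 6.41-fold lower and the class I histocompatibility gene H2-K1 6.84-fold lower.

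By list, retinoid handling had a median log2 ratio of 1.26, with 7 of 8 genes at least 1.5-fold higher in A/J and 0 lower, among them Lrat, which esterifies retinol, at 4.76-fold. Carbohydrate digestion and sugar metabolism had a median of 0.37 over 15 genes, with the fructose carrier Slc2a5 at 2.71-fold. Xenobiotic metabolism had a median of 0.37 over 27 genes, with Cyp2j6 4.56-fold higher and Cyp1a1 at least 5.86-fold lower. Peroxisomal beta-oxidation had a median of 0.46, with 7 of 17 genes at least 1.5-fold higher. Antimicrobial and regenerating proteins had a median of -1.15, with 7 of 11 at least 1.5-fold lower in A/J and 0 higher. Interferon-induced genes had a median of -0.81, with 13 of 19 at least 1.5-fold lower and 0 higher, and T cell markers had a median of -0.94, with 7 of 11 lower and 0 higher. Cholesterol synthesis had a median of -0.44, with 7 of 19 at least 1.5-fold lower and 3 higher. These last 4 lists were low in A/J against the array with the 18S signal of 11010. Between the high-fat arrays their medians were nearer to 0 or above it, at -0.21, -0.36, 0.11 and -0.09, the last with a sign that changes without scaling. Each of the 8 low-fat medians lay outside the central 95% of random lists, and over the 41 lists 8 lay above it and 7 below. Markers of cell and tissue types lay outside it too, with smooth muscle at 0.50, distal small intestine at 0.70 and Paneth cells at -0.51, as did proliferation genes at -0.31.

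On low-fat 241 genes were at least 2-fold higher in A/J and 212 lower, of which 37 and 34 are bounds. In another measured probe set, 50 of 82 higher and 31 of 61 lower genes differed by at least 1.5-fold the same way. With the signals left unscaled the counts were 396 higher and 154 lower.

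On the high-fat diet the same comparison asked how the strains differed after 2 weeks of fat feeding. Cd36 was 7.95-fold higher in A/J, Bco1 9.14-fold, Scarb1 4.12-fold and Pck1 at least 13.6-fold. St3gal4 was 105-fold lower in A/J, Reg2 41.9-fold lower, H2-K1 8.36-fold lower and the chemokine Ccl20 13.7-fold lower. Retinoid handling again had a median above 0, of 0.81 over 8 genes, PPAR-alpha targets had a median of 0.44, with 9 of 21 genes at least 1.5-fold higher and 0 lower, and mitochondrial beta-oxidation 0.33 over 19. Interferon-induced genes had a median of -0.36, with 6 of 19 at least 1.5-fold lower. The 5' 18S signal differed between these arrays too, at 84.4 on A/J high-fat and 1675 on C57BL/6J high-fat. Heat shock and unfolded protein response genes had a median of -0.37, with 8 of 22 at least 1.5-fold lower and 1 higher, and the Hsp70 gene Hspa1b 7.14-fold lower. B and plasma cell markers had a median of 0.62 and distal small intestine markers 0.96. The T cell markers had a median of 0.11 on this diet and xenobiotic metabolism 0.106, both inside the central 95% of random lists. The exocrine pancreas list had a median of -6.15, with 13 of 14 at least 2-fold lower on the A/J high-fat array.

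On high-fat 155 genes were at least 2-fold higher in A/J and 193 lower, with 25 and 50 as bounds, and 180 were lower without the exocrine pancreas list. In another measured probe set, 30 of 47 higher and 37 of 56 lower genes differed by at least 1.5-fold the same way. With the signals left unscaled the counts were 376 higher and 120 lower.

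The mean difference between the strains over the 2 diets was tested with limma as a strain term over all 4 arrays, which does not require a gene to differ on each diet. At a Benjamini-Hochberg adjusted p under 0.05, 308 genes were higher in A/J and 296 lower, out of 8036. St3gal4 was lower by -6.80 on the log2 scale (SE 0.196, limma adjusted p = 1.45e-09). Among genes of nutrient handling, Pck1 was higher by at least 3.86 (limma adjusted p = 6.17e-07), Bco1 by 3.50 (limma adjusted p = 2.16e-06), Cd36 by 3.09 (limma adjusted p = 2.79e-06) and Scarb1 by 3.03 (SE 0.345). Slc5a4b, of the family of sodium-coupled sugar transporters, was higher in A/J by 2.38. Some named genes of defence and immunity were lower in A/J: Reg2 at -4.49 (SE 0.325, limma adjusted p = 5.68e-06), H2-K1 at -2.92 (limma adjusted p = 3.68e-06), Nos2 at -2.43 or lower and Gzma at -2.28. The strains carry different H2 haplotypes, and other genes of that region went both ways, with H2-Q2 at -2.79 or lower and H2-T18 at 2.5. The chaperone genes Hspa1b and Hsph1 were lower in A/J, at -2.58 and -1.79. Me1 was higher by 1.20 (limma adjusted p = 0.0026), although another of its probe sets gave a log2 ratio of -0.54 on high-fat.

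Clock genes split in both directions. The output regulator Dbp was higher in A/J by at least 3.0 (limma adjusted p = 3.46e-06), Nr1d2 by 1.84, Tef by 1.78 and Nr1d1 by 1.51, while Npas2 lay at -1.92 or lower, Arntl at -1.45 and Nfil3 at -1.44 or lower. Of 14 measured clock genes, 5 were higher and 4 lower over all genes, and the same numbers held when adjusted over the list alone.

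Counting list members over all genes, 7 of 19 interferon-induced genes were lower in A/J, and 13 when adjusted over the list alone; their median was -0.81 on low-fat, against the array with the 18S signal of 11010, and -0.36 on high-fat. Antimicrobial and regenerating proteins had 5 of 11 lower, and 6 lower and 1 higher when adjusted over the list alone; their median was -1.15 on low-fat and -0.21 on high-fat. T cell markers had 4 of 11 lower, and 4 lower and 1 higher when adjusted over the list alone; their median was -0.94 on low-fat, against the array with the 18S signal of 11010, and 0.11 on high-fat. The exocrine pancreas list had 4 of 14 lower, and 13 when adjusted over the list alone, although 0 of the 14 were even 1.5-fold apart on low-fat. B and plasma cell markers had 2 of 9 higher and 1 lower, and 4 and 1 when adjusted over the list alone. Heat shock genes had 5 of 22 lower and 1 higher, and 6 and 1 when adjusted over the list alone. Retinoid handling had 4 of 8 higher, and 7 when adjusted over the list alone. PPAR-alpha targets had 7 of 21 higher and carbohydrate genes 4 of 15, and neither number moved when adjusted over the list alone. Xenobiotic metabolism had 5 of 27 higher and 1 lower, and 7 and 2 when adjusted over the list alone.

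By size, 90 genes were at least 2-fold higher in A/J on both diets and 97 lower, where independent lists would share 5.51 and 6.03. The strain ratios on the 2 diets shared no array and correlated across genes with r = 0.518, and 0.572 without the exocrine pancreas list. Unscaled signals gave 157 and 64 genes by size, and 596 higher and 141 lower by limma. With an unadjusted p under 0.05, 1729 genes differed by limma. A fit with an array left out can hold 1 factor only, and with strain as the only factor all 4 arrays gave 144 genes and 1369 at the unadjusted threshold. The diet difference enters the error of that fit. Leaving out any of the 4 arrays from it leaves 1 array of a strain, so this cannot check the strain genes.

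**Figure D3:**
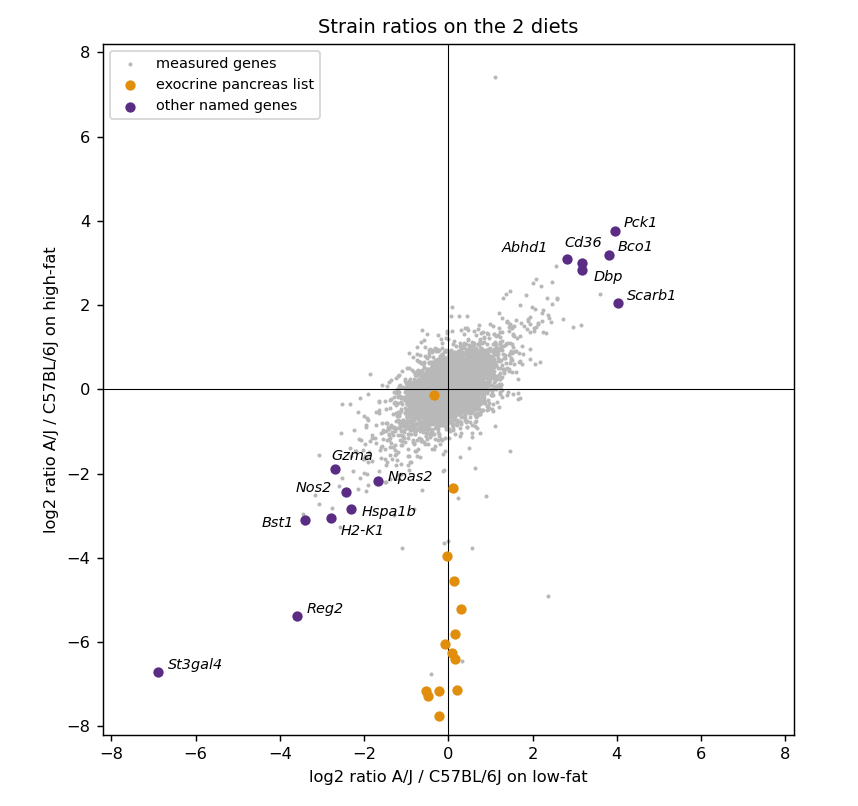
Log2 ratio of A/J to C57BL/6J signal on low-fat (x axis) against high-fat (y axis) for the 8036 measured genes (grey), with the exocrine pancreas list in orange and other named genes in purple; each point is 1 gene from 1 array per group, drawn at its bound where a side was at the floor. St3gal4 lies at -6.88 and -6.71, and 13 pancreas genes lie low on the y axis only.

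**Figure D4:**
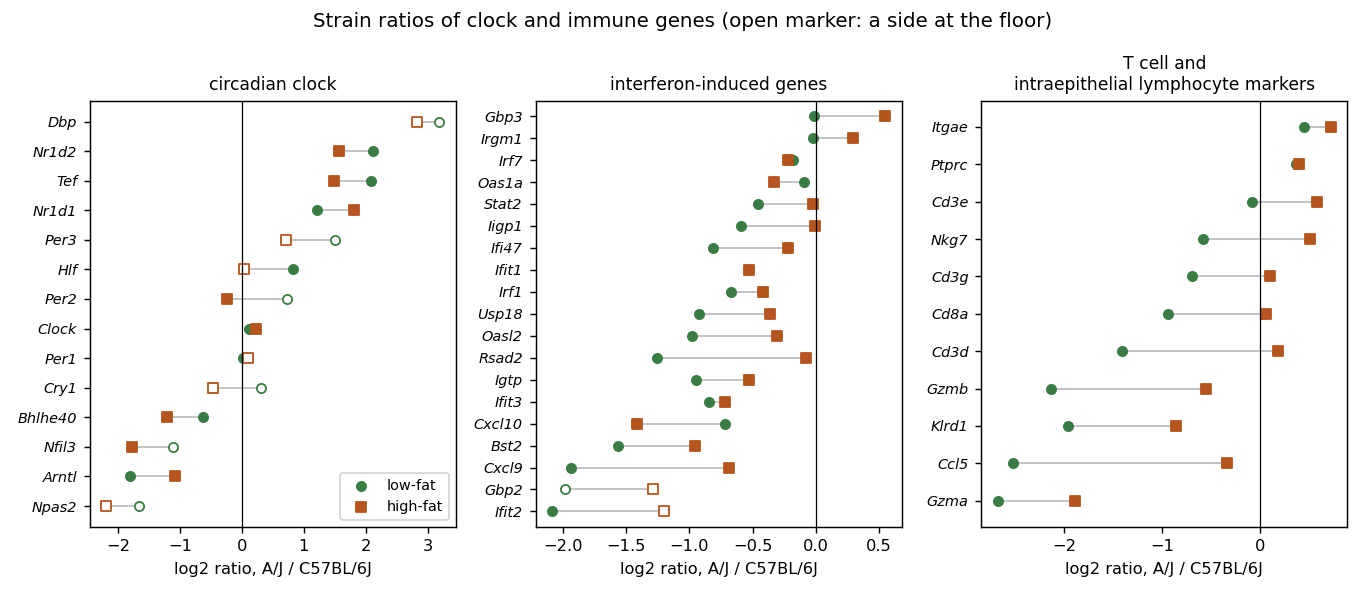
Log2 ratio of A/J to C57BL/6J signal for measured genes of the clock, interferon-induced and T cell lists on low-fat (circles) and high-fat (squares), with 1 array per group, a grey line joining the diets and open markers where a side was at the floor. List medians on low-fat and high-fat were 0.52 and 0.07 for the clock, -0.81 and -0.36 for interferon and -0.94 and 0.11 for T cell genes.

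The difference between the diet ratios of the strains asked where A/J and C57BL/6J responded differently to fat, and the design allows no test of it. The T cell markers stood highest: 6 of 11 had a diet ratio at least 2-fold higher in A/J than in C57BL/6J and 0 lower, with a median log2 difference of 1.01. Ccl5 was 1.99-fold higher with fat in A/J and 2.29-fold lower in C57BL/6J, a difference of 4.55-fold, and Cd3d and Gzmb differed by 3.02-fold and 3.01-fold the same way. Interferon-induced genes had a median difference of 0.56, with the diet ratio of Cxcl9 2.37-fold higher in A/J than in C57BL/6J. The median difference was 0.40 for immediate early genes and 0.35 for antimicrobial and regenerating proteins. These lists were high on the C57BL/6J low-fat array with the 18S signal of 11010, which enters the difference. On the lower side, retinoid handling had a median difference of -0.59. The diet ratio of 4 of its 8 genes was at least 1.5-fold lower in A/J than in C57BL/6J, and that of 0 was higher by as much. Xenobiotic metabolism had a median difference of -0.28, with diet ratios 3.54-fold lower in A/J for Cyp2c55 and 2.90-fold lower for Cyp2j6, and the clock list -0.57. The C57BL/6J low-fat array enters these lists too. The xenobiotic median was 0.425 for diet in C57BL/6J and 0.37 for strain on low-fat, both with that array. Without that array it was 0.036 for diet in A/J and 0.106 for strain on high-fat. Scarb1 was 2.54-fold lower with fat in A/J and 1.56-fold higher in C57BL/6J, a difference of 3.96-fold. The unfolded protein response gene Herpud1 was 1.75-fold lower with fat in A/J and 2.15-fold higher in C57BL/6J, while another of its probe sets gave log2 diet ratios of -0.26 and 0.32. The PPAR-alpha targets had a median difference of 0.15 and the mitochondrial beta-oxidation genes 0.05, both inside the central 95% of random lists. Paneth cell markers, at 0.415 over 6 genes, lay above that range, and fibroblast markers, at -0.451 over 9 genes, lay below it.

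For 138 genes the diet ratio was at least 2-fold higher in A/J and for 173 lower, or 160 without the exocrine pancreas list, whose median difference was -6.17. With a floor of 50 the counts were 321 and 427, and with unscaled signals 233 and 124.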

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

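The tests of a more distal piece of intestine, of an A/J-only response, of clock phase, of probe variants in clock genes and of probe variants as the only cause of the strain differences were chosen only after the result was seen.

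A set of genes moved at least 2-fold in opposite directions with diet, down in A/J and up in C57BL/6J, and the difference between the strains was not tested. As the diet log2 ratio in A/J minus that in C57BL/6J, the values were -2.66 for the chemokine Ccl20, -3.54 for the trefoil peptide Tff2 and -7.28 for the gastrokine Gkn2. They were -6.76 for syncollin (Sycn), -4.34 for the zymogen granule glycoprotein Gp2 and -3.43 for Cuzd1, all 3 made in pancreatic acinar cells. The exocrine pancreas list stood out in the same way, with a difference of -6.08 between its diet medians. Except for Ccl20, these values hold genes whose A/J high-fat signal was at the floor, so that the true difference is at least as large.

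Signals also changed with diet in probe sets listed with several genes, which no comparison used, and these differences were not tested. In A/J the log2 ratio of high-fat to low-fat was 2.85, 3.90 and at least 2.13 for 3 such probe sets, the last against a low-fat signal under the floor. In C57BL/6J their ratios were 2.24, at least 1.87 and 0.07 in the same order.

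The pancreas pattern lies in the A/J high-fat array alone. A shift of that pool towards distal intestine was argued against. Proximal markers had a median log2 ratio of 0.03 and the 4 distal markers -0.57, where such a shift would raise the distal ones. Loss of only the most proximal end stays open, since these lists were not made to show it. Gkn2, normally made by the stomach surface epithelium, and Tff2 were also at least 2-fold lower on that array than on A/J low-fat. Pancreatic tissue carried into the other 3 pools stays open. Over 10 acinar genes outside the list the median was -0.62 against the mean of the other arrays, between the bounds set beforehand. Sycn was at -5.72 and Gp2 at -3.27, but Nr5a2 at 0.49 and Dnase1 at 0.89. Whether the mucosa itself makes some of these genes was not tested, so those that were higher need not argue against it. An A/J-only response to fat also stays open, because that group has 1 array, and in C57BL/6J the list was higher on high-fat with a median of 0.68. These explanations cannot be told apart without another A/J high-fat pool.

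The clock genes differed between the strains in a pattern that may reflect a difference in clock phase. Genes that peak towards evening had a median log2 ratio of A/J to C57BL/6J of 1.35 on low-fat and 1.09 on high-fat, and genes that peak towards morning -1.11 and -1.09, so that the smaller gap was 2.18 over 8 and 5 genes. Sequence variants under the probes as the whole cause were argued against, since 4 of 14 clock genes (Dbp, Nr1d1, Nr1d2 and Tef) were at least 2-fold higher in A/J on both diets, and 3 were lower. The hour at which tissue was taken is not given in the sources used here, so an inherited difference and a difference in sampling or feeding time both stay open, untested.

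A/J variants under probes designed on other sequence could lower the A/J signal of single genes. Variants that only lower the A/J signal were argued against as the single cause of all strain differences, since 48.1% of the 187 genes at least 2-fold apart on both diets were higher in A/J (90 genes, interval 41.1% to 55.3%). Intervals in this paragraph are 95% Wilson intervals over genes, which are not independent, so they do not measure a spread between mice. The share depends on scaling, with 157 higher and 64 lower on unscaled signals. For genes lower in A/J they stay open: of 30 with another measured probe set, 15 (50%, interval 33.2% to 66.9%) were at least 1.5-fold lower in it on both diets. Among genes higher in A/J, 21 of 29 (72.4%, interval 54.3% to 85.3%) were at least 1.5-fold higher in it, and the 2 intervals overlap. Large single-gene values such as that of St3gal4 may therefore hold some probe effect. H2-K1 was lower in another probe set too. Since the strains carry different H2 haplotypes, variants could lie under both of its probe sets, so this cannot decide the question for H2-K1. A true strain difference is untested beyond this.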

How the results depend on the processing

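Leaving out the exocrine pancreas list, and the form of leave-one-out with 1 factor only, were chosen after the data were seen. No paired analysis was possible because each pool was a separate group. Of 6425 ratios of named genes under the alternatives, 6173 kept their direction and side of 2-fold, and 3 reversed. Reversed were Ighm (diet difference 0.12 with the mean of probe sets), Me1 (strain on high-fat -0.54) and Polr3d (A/J diet 0.12), the last 2 without the shared probe sets, where another probe set stands for the gene. Among list medians outside the central 95% of random lists, the C57BL/6J diet median of heat shock genes reversed to -0.001 with no scaling, and that of adipocyte markers to -0.045 without shared probe sets; sign changes of medians inside it were not counted as reversals. Of 1415 list medians 237 moved, 110 of them with no scaling. No scaling moved the median of all genes to 0.20 for strain on low-fat, 0.32 on high-fat, -0.15 for diet in C57BL/6J and 0.12 for the diet difference. Its counts were 396 higher and 154 lower for strain on low-fat, 376 and 120 on high-fat, 60 and 100 for diet in C57BL/6J, 157 and 64 on both diets, and 233 and 124 for the diet difference. The floor of 50 gave 143 higher and 204 lower for diet in A/J, 152 and 141 in C57BL/6J, 397 and 321 for strain on low-fat, 247 and 297 on high-fat, 321 and 427 for the diet difference, and 14 lower in both strains. The floor of 200 gave 40 and 47 for diet in A/J, 25 lower in C57BL/6J, 81 and 84 for the difference and 3 lower in both strains. A lower floor lets dimmer genes reach 2-fold. The pseudocount gave 143 lower for diet in A/J, and 240 and 335 for the difference. Without shared probe sets 12 genes were higher with fat in both strains. By limma, strain genes numbered 342 with the floor of 50, 386 with the mean of probe sets, 284 without shared probe sets and 144 with 1 factor (1369 unadjusted). They were 0 with the floor of 200 (1316 unadjusted) and 0 with no filter (1434 unadjusted), where many values tied at the floor leave 0.502 and 0.375 prior degrees of freedom against 11.1. Diet genes numbered 21 with quantile normalization, 15 with no scaling, 12 with the floor of 50, 103 with the pseudocount, 9 with the mean of probe sets, 6 without shared probe sets and 123 with the trend. They were 0 with the floor of 200 (825 unadjusted), 0 with no filter (979) and 0 with 1 factor (213). Leaving out each array from the fit with 1 factor cannot check the strain or diet genes. The arm left with 1 array is assumed to vary like the other, fewer arrays were tested, and the factor left out enters the error. Apart from what these constructions show, the cause was not tested.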

Other observations

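Some lists are given here in more detail. Smooth muscle markers had a median log2 ratio of -0.47 over 9 genes for diet in A/J, with 2 at least 1.5-fold lower and 0 higher, and the smooth muscle actin Actg2 was 1.49-fold lower. B and plasma cell markers had a median of 0.62 over 9 genes for A/J against C57BL/6J on high-fat, with 5 at least 1.5-fold higher and 2 lower. Proliferation genes had a median of -0.31 over 24 genes for A/J against C57BL/6J on low-fat, with 9 at least 1.5-fold lower and 0 higher. Fibroblast markers had a median of 0.29 over 9 genes for diet in C57BL/6J, where the growth factor receptor Pdgfra was 1.74-fold higher.

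Markers of the distal small intestine had medians of 0.70 and 0.96 over 4 genes for A/J against C57BL/6J on low-fat and high-fat. By limma over all genes 2 of them were higher in A/J, the vitamin B12 receptor Cubn by 1.83 (limma adjusted p = 0.00019) and the guanylin gene Guca2a by 1.5 (limma adjusted p = 0.00048), and the same 2 passed when adjusted over the list alone. The stem cell marker Prom1 was lower in A/J, at -1.47, and the mast cell protease Mcpt2 was higher, by at least 1.74. The carbonic anhydrase Car4, on the colon list, rose with fat by 1.02 (limma adjusted p = 0.0421).

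A single antimicrobial peptide gene, Defa31, had a scaled signal of 214 on A/J low-fat and 17160 on A/J high-fat, against 6 and 52 in C57BL/6J. Its probe set is marked as shared between similar transcripts, so the value may not belong to Defa31 alone.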
